A study of Mus musculus with 26 samples.

How the data were processed

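RNA was sequenced from 26 libraries of mouse bone marrow cells purified by flow cytometry, made per the labels' protocols from poly-A RNA extracted with Qiazol and a miRNeasy Micro kit and amplified with SMART-seq2, a method for small cell numbers that reads full-length transcripts without molecular identifiers and without keeping strand. Groups, replicate numbers and cell types were taken from the labels. Per the labels, the records were updated after deposit because some raw files had not been matched to the right samples. Whether the table analysed here was affected is not given in the sources used here. The submitters' processing notes name bcl2fastq 2.20, kallisto 0.440, DESeq2 1.20.0 and the mouse genome mm10, without saying what each was used for.

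The deposited table holds a signal per gene in normalized counts, not raw counts: its values are not whole, and its columns sum to 12110000 to 13770000. It has 17977 rows, and a column for each of the 26 libraries, with no other column. Of the row names, 23 are spreadsheet dates in place of gene symbols, 2 of these names repeated, and 1445 are bare identifiers; 16438 matched the gene names used here. Which of the tools made these values is not given in the sources used here. The values of most low-count genes in a library are multiples of one step, but for many genes they are not, so whole reads were not recovered and tests for counts were not used. The design written beforehand had assumed raw counts and a negative binomial test; limma, the pseudocount and the filter replaced it once the unit was known. The depth of a library was estimated as its sum divided by the value of 1 read, taken as the smallest of the 5 commonest values under 20. This gave 3410000 to 28560000 reads. Amplified reads are not independent molecules, so depth sets only the counting error.

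Values were analysed as log2(normalized count + 1), so a fold change is on that scale and understates the change of genes with low values. Genes entered a test if they reached a value of 10 in at least as many libraries as the smallest group holds. Differences were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend of the variance, robust), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. F1T was compared with F1R in each cell type on its own, so that each population had its own spread. Cell types were compared in 1 fit of the 26 libraries with a mean per group, averaging F1T and F1R, and genes were called with an absolute log2 fold change of at least 1 besides. The same fit tested whether the effect of the father differed between cell types. A positive difference means higher in F1T, or higher in the more mature cell type.

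Before the data were examined, 38 lists of genes for pathways and cell types were fixed, among them markers of cells that the sorted populations could also hold. Lists with at least 3 tested members were tested with camera, which compares a list with all other genes, with a preset correlation between genes of 0.01, and again with an estimated correlation; fry tested whether a list's genes move, on balance, one way. Scores were the mean log2 CPM of a list in each library, after adding 1 and scaling by library total, and were compared by exact two-sided permutation tests with adjustment over the lists in each cell type. Genes named in the F1T and F1R comparisons follow a rule fixed beforehand: the called genes with the largest changes, or, where none was called, up to 5 genes per direction and 2 per list with the smallest p, given as values, and a fixed set of immune and sex-linked genes. In the cell type comparisons these were the 10 largest increases and decreases with an average log2 CPM of at least 3 and 10 fixed markers; the list members named beside their list were chosen after their values were seen. S100a8, S100a9 and the levels of Cd34 and Mpo in single libraries were also chosen after their values were seen. Coordinates are those of the GENCODE annotation of GRCm38, the assembly that mm10 denotes, matched by gene symbol. Because the libraries keep no strand, named genes with at least 10% of their exonic bases shared with another annotated gene are uncertain: Csf1r, Hist1h2ae, Itgam, Lpcat2, Mpo, Pagr1a, Prss57, Rpl31, Rps10, S100a4 and Tnfsf13. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

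The tests of single genes were tried first on simulated data with known changes of 1.5, 2 and 4-fold. The data were made from the real genes' means, their spread within groups and the libraries' values of 1 read. In GMP, 64, 64 and 65 tested genes were changed by these folds in the same data, and genes were drawn independently. Adjustment is more lenient when many genes change together, so the shares recovered may overstate those for few changed genes. Across cell types, each simulated gene had 1 mean over all 26 libraries, without its difference between cell types. The list tests were tried only for F1T against F1R, with the ribosomal protein genes raised by 0.3 on the log2 scale. The permutation tests of scores and the correlations of effects were not tried on simulated data. The alternatives fixed beforehand were other scalings, no filter or another filter, voom with sample quality weights, 1 fit of all libraries for the F1T and F1R comparisons, other thresholds, a block for the replicate number, and leaving out each library in turn. Chosen after seeing the data were pseudocounts of 0.5 and 4, quantile normalization, a mean value of at least 100, array weights, other scalings of the list tests, and leaving out the libraries numbered 44 and 45.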

Results

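Gene expression was measured by RNA-seq in 3 populations of bone marrow cells from mice whose fathers had either recovered from a sublethal infection with the fungus Candida albicans (offspring named F1T) or received a mock injection of buffer (offspring named F1R). The populations were granulocyte macrophage progenitors (GMP), which give rise to granulocytes and monocytes, common monocyte progenitors (cMOP), the next stage of monocyte development, and monocytes with high surface Ly6C (Ly6Ch), the inflammatory monocytes that cMOP produce. All were purified by flow cytometry. There were 3 F1T and 3 F1R libraries of GMP and 5 of each kind for cMOP and Ly6Ch, 26 in all. The comparison of F1T with F1R addresses whether an infection of the father leaves a trace in the monocyte lineage of uninfected offspring.

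The values were normalized counts, and each library summed to between 12110000 and 13770000. The reads behind each library were estimated from the value that 1 read takes in it, and all these totals are rounded to 10000. The median was 10940000 reads in GMP F1T, with a range of 8480000 to 20710000, and 11170000 in GMP F1R, with a range of 9900000 to 19490000. In cMOP the medians were 17110000 in F1T, between 3810000 and 28560000, and 17640000 in F1R, between 12210000 and 24460000. Ly6Ch F1T had a median of 15370000, between 6570000 and 23350000, and Ly6Ch F1R one of 9230000, between 3410000 and 18940000. Between 13716 and 16598 genes were detected per library. The labels do not say that the libraries of a group came from separate animals, so every p-value measures only the spread between these samples, which can be technical. They name no litter either, so a difference between litters cannot be told apart from an effect of the father's infection.

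The cell types separated on the first principal component, which held 56.4% of the variance; the second held 9.85%. GMP libraries lay between −104 and −89.9 on the first component, cMOP libraries between −43.3 and −20.3, and Ly6Ch libraries between 65.4 and 99.6. The libraries numbered 44 and 45 of F1T lay at 65.4 and 67.0 in Ly6Ch, apart from the other Ly6Ch libraries, which all reached at least 80.8. They lay at −38.5 and −43.3 in cMOP, where the other libraries lay at −29.4 or higher. The correlation across genes of log2 values between libraries of one cell type was 0.965 to 0.982 in GMP, 0.935 to 0.973 in cMOP and 0.938 to 0.976 in Ly6Ch. In both cMOP and Ly6Ch the closest pair was F1T 44 with F1T 45.

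**Figure D1:**
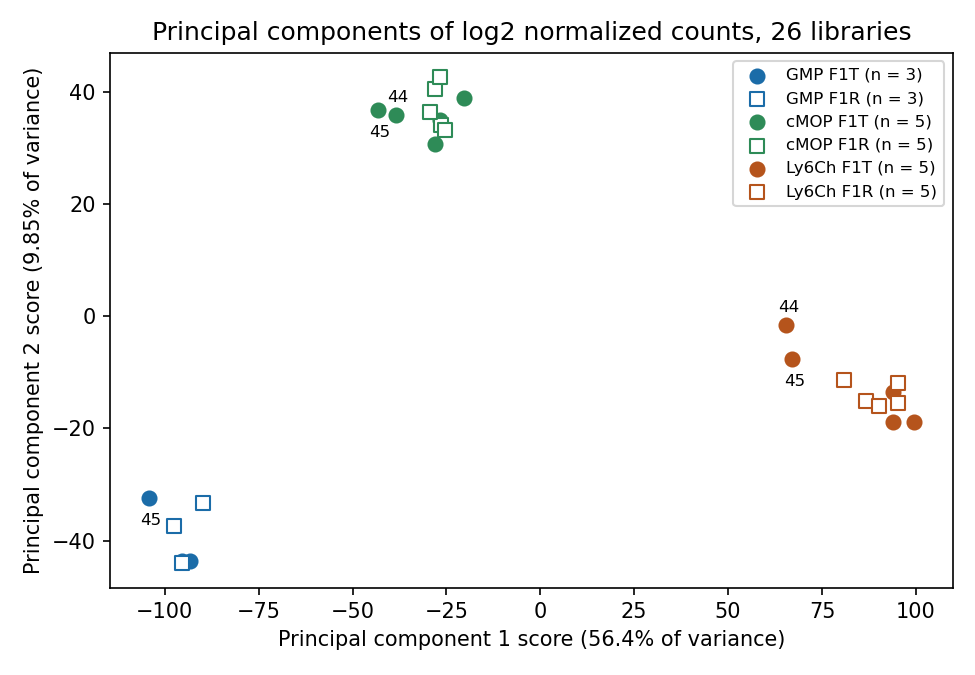
Scores of the 26 libraries on the first (horizontal) and second (vertical) principal components of log2 normalized counts, in percent of variance; filled circles are F1T, open squares F1R, and libraries numbered 44 and 45 are labelled. The 3 cell types lie apart, F1T and F1R overlap, and Ly6Ch F1T 44 and 45 lie at 65.4 and 67.0 on the first component while the other Ly6Ch libraries lie at 80.8 or higher.

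From GMP to cMOP, monocyte genes rose and progenitor, megakaryocyte, erythroid and basophil genes fell. Lgals3, which encodes the lectin galectin-3 (chromosome 14, 47367751 to 47386160), was higher in cMOP by 5.21 on the log2 scale (SE 0.12, limma adjusted p = 6.19e-23). Its normalized count was 104 ± 28.2 (SD, n = 3) in GMP F1R and 3149 ± 298 (SD, n = 5) in cMOP F1R. Klf4, a transcription factor of monocyte development (chromosome 4, 55527143 to 55532466), was higher by 4.75 (SE 0.18, limma adjusted p = 4.55e-18). Ccr2, the chemokine receptor that monocytes need to leave the bone marrow (chromosome 9, 124101950 to 124113557), averaged 669 ± 180 (SD, n = 3) normalized counts in GMP F1R and 4677 ± 167 (SD, n = 5) in cMOP F1R, a log2 difference of 2.74. Csf1r, the receptor for macrophage colony-stimulating factor, rose by 2.01 on the log2 scale.

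Other large increases in cMOP were S100a4 with a log2 difference of 4.41, Tlr13 with 5.0, Ahnak with 4.70 and Adora2b with 4.20. Lilra6 (5.42), Sirpb1c (5.20), Ifi207 (4.72) and Pira2 (4.68) rose as well, and these belong to families of near-identical copies, so their values are uncertain. Among genes with an average log2 CPM of at least 3, the largest decreases were in Vat1 (−4.16), Vcam1 (−3.61), the tetraspanin gene Cd63 (−3.45), Pglyrp1 (−3.38) and the stem cell marker Prom1 (−3.19). Lpcat2 (−3.11), Syne1 (−2.96), Slco3a1 (−2.89), Wfdc21 (−2.85) and Slc28a2 (−2.81) followed. Of the markers fixed beforehand, Flt3 had a log2 difference of −1.65, Elane, which encodes neutrophil elastase, −1.01, and Cx3cr1 1.37. Kit, the receptor for stem cell factor, was lower by −1.64 (limma adjusted p = 0.0316). Mpo (−0.78, limma adjusted p = 0.00783), Cd34 (−0.70, limma adjusted p = 0.0241), Ly6c2 (0.82) and Itgam (−0.71) differed by less than the fold limit of 1. In all, 681 genes were higher and 1170 lower in cMOP among 13582 tested, and 5966 had an unadjusted p under 0.05.

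Among the 38 gene lists fixed beforehand, 18 differed between cMOP and GMP with a preset correlation between genes, 10 of them higher in cMOP, and 7 remained with an estimated correlation. Of the 7, classical monocyte genes were higher in 18 of 23 members, with 14 passing the test upward and a median log2 difference of 1.42. Their called members included F13a1, the coagulation factor XIII subunit, with a log2 difference of 2.21. Phagocytosis and lysosome genes were higher in 16 of 20 members, 7 of them past the test, such as Ctss (3.40) and Psap (2.27), with a median of 0.65. Migration and adhesion genes were higher in 13 of 16, 6 of them past the test, with a median of 0.89. All 17 stem and progenitor genes were lower, 13 past the test, with a median of −1.80. These included the transcription factor genes Gata2 (−5.38) and Mycn (−4.50). All 12 megakaryocyte genes were lower, 11 past the test and a median of −4.31, with Pf4, which encodes platelet factor 4, at −7.74. All 14 erythroid genes were lower, 8 past the test and a median of −2.73, and all 13 basophil, mast cell and eosinophil genes were lower and past the test, with a median of −3.13. Their adjusted p with an estimated correlation was 0.0152 for the classical monocyte, phagocytosis and erythroid lists, 0.0292 for migration, 9.02e-05 for the progenitor and megakaryocyte lists and 0.000525 for the basophil list.

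For the other 11 lists the call was lost with an estimated correlation. Early granule genes were lower in 11 of 12 members, 8 of them past the test, with a median of −1.12 (adjusted p = 0.10 with an estimated correlation). DNA replication genes were higher in 26 of 27 members with a median of 0.39 (adjusted p = 0.288 with an estimated correlation), and ribosomal protein genes lower in 31 of 34 with a median of −0.24 (adjusted p = 0.293). NF-kappaB genes were higher in 14 of 19 (adjusted p = 0.151 with an estimated correlation), immediate early genes in 12 of 16 (adjusted p = 0.127), fungal and bacterial recognition genes in 13 of 22 (adjusted p = 0.118), phagocyte oxidase genes in 7 of 9 (adjusted p = 0.118), cytokine receptors in 14 of 19 (adjusted p = 0.170) and Ly6C-low monocyte genes in 11 of 16 (adjusted p = 0.331). Imprinted genes were lower in 12 of 15 (adjusted p = 0.0893 with an estimated correlation) and tissue macrophage genes in 9 of 12 (adjusted p = 0.10).

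From cMOP to Ly6Ch, interferon-response, pathogen-recognition, oxidase and lysosomal genes rose, while granule, progenitor and ribosomal protein genes fell. Fn1, which encodes fibronectin (chromosome 1, 71585520 to 71653200), was higher in Ly6Ch by 5.54 on the log2 scale (SE 0.14, limma adjusted p = 4.85e-22), from 684 ± 39.2 to 33364 ± 3136 normalized counts in F1R (SD, n = 5 each). Ccr2 rose further, to 26644 ± 3373 (SD, n = 5) in Ly6Ch F1R, a log2 difference of 2.50. Kit (chromosome 5, 75574916 to 75656722) was lower by −7.36 (SE 0.51, limma adjusted p = 3.29e-12), from 587 ± 141 in cMOP F1T to 7.76 ± 9.33 in Ly6Ch F1T (SD, n = 5 each). Mpo, the myeloperoxidase gene (chromosome 11, 87793581 to 87804413), was lower by −5.01 (SE 0.19), from 263945 ± 12287 in cMOP F1R to 7522 ± 1770 in Ly6Ch F1R (SD, n = 5 each).

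The other large increases were in the Src-family kinase gene Fgr (5.32), Wfdc17 (5.23), the interferon-inducible Samd9l (5.21), Camk1d (5.20), Plbd1 (5.15) and Ifi27l2a (4.88), and in Ifi207 (5.24), Clec4a1 (5.13) and Sirpb1c (4.89), which have near-identical copies and are uncertain. The other large decreases were in the neutrophil granule genes Camp (−7.10), Ngp (−6.60) and Ltf (−5.54), the cyclin gene Ccnd2 (−5.83), Nkg7 (−4.92), Prss57 (−4.82), Muc13 (−4.81) and Hdc, the histamine-forming enzyme (−4.60). Of the fixed markers, Itgam, which encodes CD11b, rose by 3.56, Cx3cr1 by 2.46, Flt3 by 1.14 and Csf1r by 1.02, while Cd34 had a log2 difference of −3.24 and Elane of −3.70. Ly6c2 differed by −0.36, under the fold limit. Altogether 1791 genes were higher and 1484 lower in Ly6Ch among 13582 tested, and 8735 had an unadjusted p under 0.05.

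Of the 38 lists, 21 differed between Ly6Ch and cMOP with a preset correlation, 12 of them higher in Ly6Ch, and 11 remained with an estimated correlation. Type I interferon response genes were higher in 28 of 29 members, 27 past the test, with a median log2 difference of 2.68 (adjusted p = 0.0111 with an estimated correlation). Examples were the transcription factor gene Irf7 (4.26) and the nucleic acid sensor gene Zbp1 (3.55). All 22 fungal and bacterial recognition genes were higher, 18 past the test, with a median of 1.30 (adjusted p = 0.000387 with an estimated correlation), among them Tlr2 (2.32) and Itgb2 (2.64). NF-kappaB genes were higher in 18 of 19 (12 past the test, median 1.71, adjusted p = 0.0111). All 9 phagocyte oxidase genes were higher, 6 past the test, with a median of 1.37 (adjusted p = 0.0269). These included Cybb, a subunit of the oxidase (2.57), and Lyz2, lysozyme (3.96). All 20 phagocytosis and lysosome genes were higher, 11 past the test (median 1.33, adjusted p = 0.0177), as were 14 of 16 migration genes (8 past the test, median 1.13, adjusted p = 0.0177), 17 of 19 cytokine receptors (8 past the test, median 0.87, adjusted p = 0.0450) and 21 of 23 classical monocyte genes (16 past the test, median 2.30, adjusted p = 0.00919). Lower were 34 of 34 ribosomal protein genes (4 past the test, median −0.73, adjusted p = 0.0266), 14 of 17 stem and progenitor genes (11 past the test, median −2.91, adjusted p = 0.00542), with Cdk6 at −3.14 and Myc at −2.98, and 11 of 12 early granule genes (10 past the test, median −3.58, adjusted p = 0.0450).

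The 10 lists that were called with the preset correlation alone had higher interferon-gamma-induced genes (15 of 18, adjusted p = 0.0810 with an estimated correlation), immediate early genes (14 of 16, 0.0826 likewise), myeloid lineage factors (14 of 19, adjusted p = 0.0892) and Ly6C-low monocyte genes (12 of 16, adjusted p = 0.178). Lower were 26 of 27 DNA replication genes, 12 of them past the test (adjusted p = 0.0892 with an estimated correlation), 36 of 38 nuclear oxidative phosphorylation genes (adjusted p = 0.280), all 15 mitochondrially encoded genes (adjusted p = 0.414), 8 of 9 heat shock genes (adjusted p = 0.274), 15 of 17 unfolded protein response genes (adjusted p = 0.414) and 9 of 13 basophil genes (adjusted p = 0.106).

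In GMP, no gene differed between F1T and F1R after adjustment (limma, 0 of 12178 tested, smallest adjusted p = 0.669). At an unadjusted p under 0.05 there were 353 genes, 210 higher and 143 lower in F1T. These were 2.90% of the genes tested, where chance alone gives a share of 0.05. The smallest p among higher genes belonged to Mrgpra2b (chromosome 7, 47463806 to 47528862), with 1257 ± 51.3 normalized counts in F1T and 690 ± 139 in F1R (SD, n = 3 each), a log2 difference of 0.88 (SE 0.15, unadjusted p = 5.49e-05 by limma). It has near-identical relatives and is uncertain. Lcn2, which encodes the iron-binding granule protein lipocalin-2 (chromosome 2, 32384633 to 32388252), had 1208 ± 129 in F1T and 720 ± 96.8 in F1R (SD, n = 3 each), a log2 difference of 0.75. The log2 difference was 0.86 for Kif13b, 0.85 for the histone gene Hist1h2ae and 0.94 for Pagr1a (uncertain, since an annotated gene covers nearly all its exons), and −1.42 for Unc13a, −1.14 for Lime1, −1.27 for Retnlg, −0.74 for the basophil protease gene Prss34 and −1.08 for Bhlha15. With array weights, chosen after the data were seen, 2 genes passed, Lcn2 and Mrgpra2b, while voom with sample quality weights, fixed beforehand, gave 0 (smallest adjusted p = 0.142). Without F1T 45, 3 passed (Hist1h1e, Tfrc and mt-Rnr1, chosen after their values were seen). In simulated data with many genes changed together, 57.8% of genes changed 2-fold were recovered at this group size, with 4 false calls. The share for few changed genes may be lower.

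Of 37 lists tested in GMP, 11 differed with a preset correlation, and none with an estimated correlation or with fry, a test of whether a list's genes move one way. Late neutrophil genes were higher in F1T in 14 of 18 members with a median of 0.23 (adjusted p = 0.000492 preset, adjusted p = 0.617 with an estimated correlation). Adjusted over the list alone, 4 of them were higher and 1 lower, against 0 over all genes. All 12 early granule genes were higher, with a median of 0.15 (adjusted p = 0.799 with an estimated correlation). Cholesterol synthesis genes were higher in 17 of 21 (median 0.20, adjusted p = 0.799 with an estimated correlation), mitochondrially encoded genes in 14 of 15 (median 0.17, adjusted p = 0.799), recognition genes in 15 of 21 (median 0.12, adjusted p = 0.612) and ribosomal protein genes in 30 of 34 (median 0.07, adjusted p = 0.932). MHC class II genes were lower in 9 of 10 (median −0.24, adjusted p = 0.612 with an estimated correlation); Cd74, the class II invariant chain, had 438 ± 144 in F1T and 755 ± 198 in F1R (SD, n = 3 each). Type I interferon genes were lower in 22 of 27 (median −0.15), Ly6C-low monocyte genes in 7 of 9 (median −0.54), tissue macrophage genes in 9 of 12 (median −0.69) and basophil genes in 10 of 12 (median −0.29), each with an adjusted p = 0.612 with an estimated correlation. Adjusted over the list alone, 1 basophil gene was higher and 2 lower, and 1 classical monocyte gene, Vcan, was higher (log2 difference 2.94). F1T 45 lay at −104 on the first principal component, the lowest of all GMP libraries.

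Each of the 11 calls in GMP was lost without at least 1 of the 6 libraries, with the preset correlation, and 6 lists were called in all without F1T 41. Without F1T 41 the adjusted p was 0.0832 for type I interferon (median −0.16), 0.353 for mitochondrially encoded (median 0.07), 0.0788 for recognition (median 0.14), 0.176 for late neutrophil (median 0.06) and 0.0832 for basophil genes (median −0.15). Without F1T 42 it was 0.0659 for mitochondrially encoded (median 0.09), 0.109 for recognition (median 0.12) and 0.983 for ribosomal protein genes (median 0.00026). Without F1T 45 it was 0.119 for MHC class II (median −0.09), 0.637 for cholesterol synthesis (median 0.08), 0.0917 for Ly6C-low (median −0.27), 0.191 for early granule (median 0.06) and 0.191 for basophil genes (median −0.11). Without F1R 46 it was 0.200 for type I interferon (median −0.11) and for ribosomal protein genes (median 0.05), 0.0833 for recognition (median 0.08) and 0.0529 for basophil genes (median −0.24). Without F1R 49 it was 0.0504 for recognition (median 0.11), 0.114 for late neutrophil (median 0.17) and 0.348 for early granule genes (median 0.03). Without F1R 50 it was 0.290 for mitochondrially encoded (median 0.06), 0.495 for ribosomal protein (median 0.04), 0.0735 for basophil (median −0.20) and 0.0770 for tissue macrophage genes (median −0.41). Other medians grew by over 1.5 times. The late neutrophil median was 0.41 without F1T 45 and 0.50 without F1R 50, the mitochondrially encoded one 0.32 without F1T 45, and the MHC class II one −0.45 without F1T 42. The type I interferon median was −0.27 without F1T 45 and −0.28 without F1R 49, and the ribosomal one 0.11 without F1T 41 or F1T 45 and 0.12 without F1R 49.

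In cMOP, no gene passed either (limma, 0 of 11678 tested, smallest adjusted p = 0.668). At an unadjusted p under 0.05 there were 569, with 339 higher and 230 lower. These were 4.87% of the genes tested, where chance alone gives a share of 0.05. Tnfsf13, which encodes the cytokine APRIL (chromosome 11, 69682846 to 69685784), had 871 ± 91.7 normalized counts in F1T and 585 ± 48.6 in F1R (SD, n = 5 each). All 5 F1T libraries lay above all F1R libraries, with a log2 difference of 0.57 (SE 0.12, unadjusted p = 0.000172 by limma). Its exons overlap those of the antisense gene Tnfsf13os and of the readthrough gene Tnfsfm13, so its value is uncertain. Sumf1 (0.64), Slc35f6 (0.65), Ssc4d (0.99) and Chil3 (0.66), a chitinase-like protein of monocytes and macrophages, were the other genes with the smallest p on the higher side. On the lower side were Bbx (−0.54), Fyb (−0.89), Uhrf2 (−0.49), Vps13c (−0.55) and Smchd1 (−0.44). Epx, the eosinophil peroxidase gene, had 82.0 ± 34.2 in F1T and 10.1 ± 13.7 in F1R (SD, n = 5 each), and passed when adjusted over the list alone but not over all genes. In the same way Lcn2 (0.55) and Wfdc21 (0.97) of the late neutrophil list and Chil3 of the classical monocyte list passed over their list alone. In simulated data with many genes changed together, 67.2% of genes changed 2-fold were recovered in this comparison, with 4 false calls.

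Of 36 lists tested in cMOP, 3 differed with a preset correlation and 0 with an estimated correlation or fry. Cholesterol synthesis genes were higher in F1T in 19 of 21 members with a median of 0.25 (adjusted p = 5.85e-05 preset, adjusted p = 0.954 with an estimated correlation), among them Srebf2 (0.52), the master regulator of the pathway, and Msmo1 (0.54). Glycolysis genes were higher in 15 of 18 with a median of 0.15 (adjusted p = 0.0141 preset, adjusted p = 0.954 with an estimated correlation), such as the glucose transporter gene Slc2a1 (0.57) and Hk1 (0.39). Ly6C-low monocyte genes were lower in 13 of 14 with a median of −0.36 (adjusted p = 0.00871 preset, adjusted p = 0.954 with an estimated correlation), with Cd300e at −2.22 and Ace at −1.31, or −0.62 for Ace without F1T 42. The libraries F1T 44 and F1T 45 had glycolysis scores of 8.21 and 8.12, expressed as mean log2 CPM, where the other 8 cMOP libraries had between 7.67 and 7.90. Their cholesterol scores were 5.04 and 5.28, where the others had 4.52 to 4.85. Without these 2 libraries the median was −0.06 for glycolysis, 0.07 for cholesterol synthesis and −0.05 for the Ly6C-low list, and none of the 3 was called, while 10 lists were called in all. The glycolysis call was also lost without F1T 44 (median 0.06, adjusted p = 0.246), F1T 45 (median 0.04, adjusted p = 0.251) or F1R 50 (median 0.11, adjusted p = 0.128), and the Ly6C-low call without F1T 45 (median −0.16, adjusted p = 0.177). The cholesterol median was 0.14 without F1T 45 and the Ly6C-low median −0.68 without F1R 47, both still called. The number of lists called was 6 without F1T 44, 2 without F1T 45 and 5 without F1R 46.

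In Ly6Ch, ribosomal protein genes were higher in F1T than in F1R, in 33 of 34 members with a median log2 difference of 0.29 (camera adjusted p = 6.11e-30 preset). This list was the only 1 of 37 still called with an estimated correlation (adjusted p = 0.0253) and with fry (adjusted p = 0.00246). Rpl31 (chromosome 1, 39367842 to 39371911) had 2328 ± 110 normalized counts in F1T and 1795 ± 88.5 in F1R, and Rps20 (chromosome 4, 3831334 to 3835665) had 4318 ± 349 and 3233 ± 295 (SD, n = 5 each). Exons of Rpl31 overlap those of Tbc1d8 on the other strand, which makes its value uncertain. Rps10, which shares exons with a readthrough gene, differed by 0.38, Rpl19 by 0.33 and Rplp0 by 0.32. Adjusted over the list alone 27 members were higher, and 0 over all genes tested. The mean log2 CPM of the list was 9.13 ± 0.074 in F1T and 8.90 ± 0.080 in F1R (SD, n = 5 each). The 5 F1T libraries, between 9.00 and 9.20, lay above the 5 F1R libraries, between 8.79 and 8.97. The exact two-sided permutation p was 0.00794, the smallest that 5 against 5 allows, and 0.302 after adjustment over the lists. The adjusted p with an estimated correlation rose to 0.147 without F1T 41, 0.0889 without F1T 43, 0.0667 without F1T 44, 0.0531 without F1T 45, 0.0560 without F1R 48 and 0.0610 without F1R 49. It was 0.416 without both F1T 44 and F1T 45, with the median at 0.30.

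**Figure D2:**
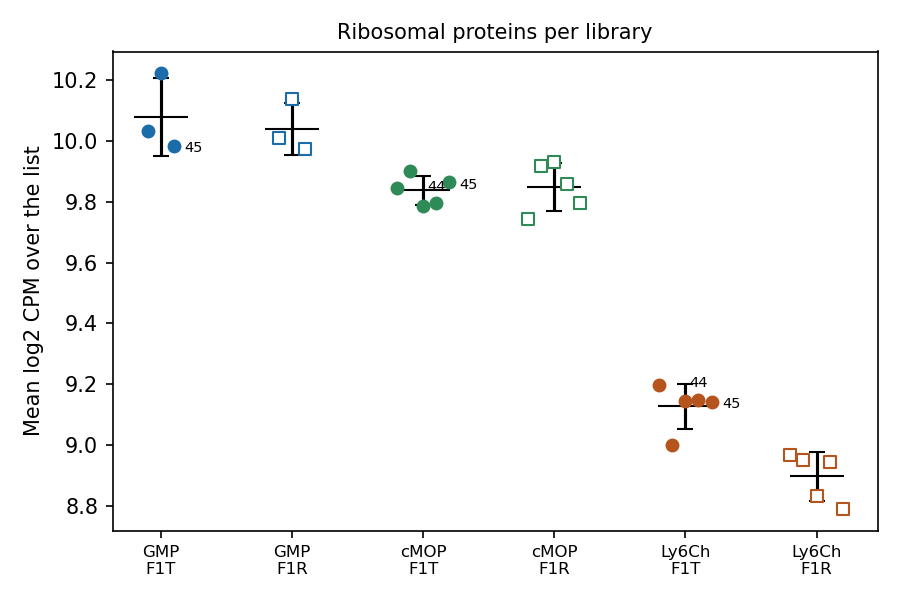
Mean log2 CPM over the 34 ribosomal protein genes (vertical axis) in each library of the 6 groups (horizontal axis); filled circles are F1T, open squares F1R, horizontal lines the group means and bars ± 1 SD, with libraries numbered 44 and 45 labelled. The Ly6Ch F1T libraries lie between 9.00 and 9.20 and the Ly6Ch F1R libraries between 8.79 and 8.97, while F1T and F1R overlap in GMP and cMOP.

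No single gene passed in Ly6Ch (limma, 0 of 11857 tested, smallest adjusted p = 0.779). At an unadjusted p under 0.05 there were 695, with 395 higher and 300 lower. These were 5.86% of the genes tested, where chance alone gives a share of 0.05. Trem2, a receptor of macrophages for lipids (chromosome 17, 48346401 to 48354147), had 1053 ± 189 normalized counts in F1T and 607 ± 124 in F1R (SD, n = 5 each), a log2 difference of 0.80 (SE 0.16, unadjusted p = 0.000207 by limma). AW112010 differed by 0.73. On the lower side were Tnrc6c (−0.53), Prex2 (−1.12), Secisbp2 (−0.48), Myo9a (−0.87) and Dpysl2 (−0.55). In simulated data with many genes changed together, 57.6% of genes changed 2-fold were recovered in this comparison, with 8 false calls.

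The other 5 lists called in Ly6Ch with a preset correlation were not called with an estimated correlation (adjusted p = 0.756 for each). All 29 type I interferon response genes were lower in F1T, with a median of −0.32 (camera adjusted p = 5.62e-11 preset). Oasl2, an interferon-induced gene, had 886 ± 278 in F1T and 1346 ± 301 in F1R (SD, n = 5 each). Nuclear oxidative phosphorylation genes were higher in 37 of 38 (median 0.13), with Ndufv1 at 0.29 and Cox4i1 at 0.20, and mitochondrially encoded genes in 14 of 15 (median 0.13), with mt-Co1 at 0.23. All 11 early granule genes were higher (median 0.31), as were 14 of 15 late neutrophil genes (median 0.36), with Wfdc21 at 3.18 and Cxcr2 at 0.75. F1T 44 and F1T 45 had late neutrophil scores of 5.24 and 4.69, where the other 8 Ly6Ch libraries had 2.57 to 3.78, and early granule scores of 6.97 and 6.61, where the others had 5.47 to 6.17. Their type I interferon scores of 5.22 and 5.05 were below those of the other libraries, which were 5.38 to 6.28. Without these 2 libraries the median was −0.15 for type I interferon genes (still called with a preset correlation), 0.06 for nuclear oxidative phosphorylation, −0.09 for early granule and 0.06 for late neutrophil genes (the last 3 not called), and 10 lists were called in all. The early granule call was also lost without F1T 44 (median 0.12, adjusted p = 0.383), F1T 45 (median 0.19, adjusted p = 0.198), F1R 48 (median 0.25, adjusted p = 0.0818) or F1R 50 (median 0.26, adjusted p = 0.0558), and the mitochondrially encoded call without F1R 49 (median 0.08, adjusted p = 0.170). The late neutrophil median was 0.20 without F1T 44, 0.21 without F1T 45, 0.55 without F1T 41 and 0.79 without F1T 42, and the mitochondrially encoded one 0.08 without F1T 44 or F1R 50, all still called. In all 11 lists were called without F1T 41, F1T 42 or F1T 43 and 9 without F1R 46.

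**Figure D3:**
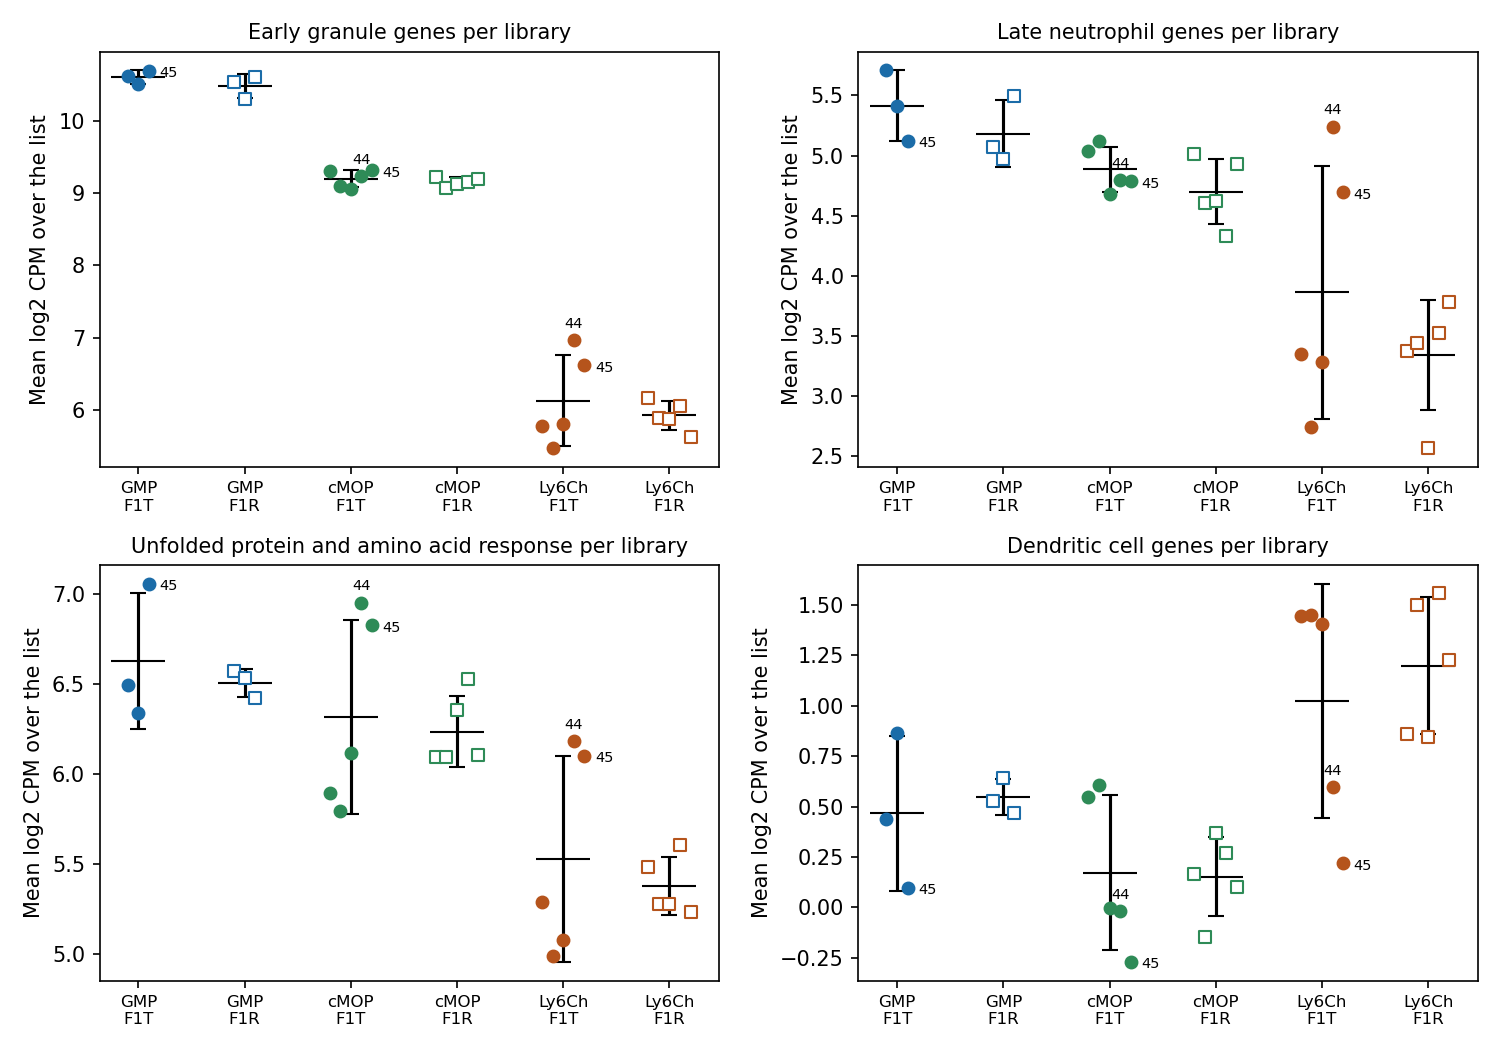
Mean log2 CPM (vertical axes) over the early granule, late neutrophil, unfolded protein and amino acid response, and dendritic cell gene lists in each library of the 6 groups (horizontal axes); filled circles are F1T, open squares F1R, horizontal lines the group means and bars ± 1 SD. The Ly6Ch F1T libraries 44 and 45 have late neutrophil scores of 5.24 and 4.69, above the 2.57 to 3.78 of the other Ly6Ch libraries.

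Genes fixed beforehand for their role in the response to the fungus or in antigen presentation did not pass in any cell type. Clec7a, which encodes the fungal receptor dectin-1, differed between F1T and F1R by 0.15 in GMP, 0.09 in cMOP and 0.08 in Ly6Ch on the log2 scale. Tnf differed by −0.25, 0.14 and 0.09, Cd74 by −0.81, −0.09 and −0.71, H2-Aa by −0.60, −1.19 and −0.99, and H2-Ab1 by −0.14, 0.13 and −0.59, in the same order. Ciita, the class II transactivator, differed by −0.81 in GMP and 0.13 in Ly6Ch, and Il1b by −0.20 in Ly6Ch. Several of these values moved by over 1.5 times without 1 library. Without Ly6Ch F1T 41, where Il1b was listed at 0, Il1b differed by 0.70, and without each other library it ranged from −0.65 (without F1T 43) to −0.09 (without F1R 50). Without cMOP F1T 42, where H2-Aa was listed at 0, H2-Aa differed by −0.22, without cMOP F1R 47 by −1.81, and without Ly6Ch F1T 44 by −0.50. Cd74 differed in Ly6Ch by −0.40 without F1T 44 and −0.39 without F1T 45, H2-Ab1 in Ly6Ch by −0.23 without F1T 45, Ciita in GMP by −0.42 without F1T 45 and −1.27 without F1T 42, and Tnf in GMP by −0.11 without F1T 42. With 1 library left out H2-Ab1 ranged from −0.21 (without F1R 49) to −0.05 (without F1R 50) in GMP and from 0.05 (without F1R 48) to 0.23 (without F1R 50) in cMOP. The sign of other values turned without 1 library or another. Clec7a ranged from −0.11 to 0.40 in GMP, −0.05 to 0.23 in cMOP and −0.10 to 0.27 in Ly6Ch, Tnf from −0.15 to 0.60 in cMOP and −0.19 to 0.24 in Ly6Ch, Cd74 from −0.38 to 0.15 in cMOP and Ciita from −0.34 to 0.69 in Ly6Ch. Il6 did not reach the filter and was not tested. The Y-linked gene Ddx3y was detected in all groups and differed by −0.15, 0.12 and −0.14. With 1 library left out it ranged from −0.23 (without F1R 50) to −0.05 (without F1R 49) in GMP, 0.02 (without F1T 43) to 0.18 (without F1T 45) in cMOP and −0.22 (without F1R 49) to −0.04 (without F1R 50) in Ly6Ch.

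The effect of the father did not differ between cell types for any gene by limma. The smallest adjusted p was 1 for cMOP against GMP (244 of 13582 genes at an unadjusted p under 0.05), 0.200 for Ly6Ch against cMOP (719) and 0.9999 for Ly6Ch against GMP (277). These counts were 1.80%, 5.29% and 2.04% of the genes tested, where chance alone gives a share of 0.05. Among genes simulated with a 2-fold difference of effect, many changed together, 34.8%, 40.9% and 30.8% were recovered, in the same order. There were 2, 6 and 3 false calls. Of 38 lists, 1, 2 and 4 differed with a preset correlation and 0 with an estimated correlation. Ribosomal protein genes were among them: the F1T difference was larger in Ly6Ch than in cMOP by a median of 0.27 (adjusted p = 0.143 with an estimated correlation, adjusted p = 0.0400 with fry, which does not compare the list with other genes) and larger than in GMP by 0.23 (adjusted p = 0.481).

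Correlations across genes of the log2 difference between F1T and F1R in one cell type with that in another were no higher than relabelled libraries often gave. Pearson's r was 0.102 and Spearman's rho 0.083 between cMOP and Ly6Ch over 11267 genes, which are not independent replicates. Relabelling the numbered libraries in the same way in both cell types gave a value as high in 100 of 252 relabellings (one-sided exact p = 0.397 for r and 0.437 for rho). For GMP with cMOP the values were 0.135 and 0.117 (exact p = 0.4 and 0.5 over 20 relabellings), and for GMP with Ly6Ch 0.071 and 0.113 (exact p = 0.4 for both). Over genes with an average log2 CPM of at least 3, r was 0.164 and rho 0.163 for GMP with Ly6Ch (exact p = 0.4 for both), 0.131 and 0.115 for GMP with cMOP (exact p = 0.5 and 0.6) and 0.116 and 0.098 for cMOP with Ly6Ch (exact p = 0.468 and 0.516). Without libraries 44 and 45, r for cMOP with Ly6Ch was 0.034 (exact p = 0.214).

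Of the scores of the 38 lists, which include markers of other cell types that the sorted populations could hold, none passed by exact permutation tests after adjustment over the lists. The smallest exact p that the design allows is 0.1 in GMP and 0.00794 in cMOP and Ly6Ch, and at these values a single list cannot pass the adjustment even with its groups fully apart. The result therefore does not show that the scores were alike. In cMOP the cholesterol score (4.94 ± 0.226 in F1T and 4.67 ± 0.121 in F1R, SD, n = 5 each) and the mitosis score (7.34 ± 0.019 and 7.41 ± 0.062, lower in F1T) each had an unadjusted exact p = 0.0476 and an adjusted p = 0.905. In GMP 6 of the 38 scores reached the smallest exact p of 0.1, which chance gives for a share of 0.1. All of these were lower in F1T. They were those of MHC class II genes (3.62 ± 0.360 in F1T and 4.02 ± 0.083 in F1R, SD, n = 3 each), tissue macrophage genes (1.51 ± 0.169 and 2.21 ± 0.393), type I interferon genes (2.62 ± 0.034 and 2.86 ± 0.063), heat shock genes (6.57 ± 0.108 and 6.78 ± 0.201), antioxidant genes (5.90 ± 0.153 and 6.10 ± 0.048) and Ly6C-low monocyte genes (0.47 ± 0.513 and 1.2 ± 0.118). Of the 13 antioxidant genes tested, 7 were higher and 6 lower in F1T, with a median log2 difference of 0.0028. The other lists named here had more members lower than higher. Only 9 of the 16 Ly6C-low monocyte genes reached the filter.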

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

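The tests of depth, of cMOP shares in single libraries, and of GMP and neutrophil cells were chosen after the results they bear on were seen; those of transcript length, of cMOP-enriched genes and of other splits of the samples were written before.

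In 15 of 322 tests, each of 1 measure in 1 group of 5 libraries, 1 library lay far from the other 4. This is about the 1 in 20 that chance gives, although the tests share libraries and are not independent. Among list scores in mean log2 CPM, replicate 42 of Ly6Ch F1T had 2.65 for NF-kappaB genes (the other 4 had 2.31 to 2.34), 9.00 for ribosomal protein genes (9.14 to 9.20) and 8.57 for classical monocyte genes (8.38 to 8.44). Replicate 45 had 9.88 for mitochondrially encoded genes in cMOP F1T (10.2 to 10.4) and 9.67 in Ly6Ch F1T (9.82 to 9.88). In Ly6Ch F1R, replicate 48 had 7.0 for MHC class I genes (7.12 to 7.15), replicate 47 had 4.03 for Ly6C-low monocyte genes (3.42 to 3.59) and replicate 46 had −0.40 for erythroid genes (−1.93 to −1.51). In cMOP F1R, replicate 49 had 0.62 for B lineage genes (−0.54 to −0.28). Among log2 values of single genes, replicate 42 of cMOP F1T had 0.64 for Ace (3.57 to 4.34) and 0 for H2-Aa (4.29 to 5.83). In Ly6Ch F1T, replicate 41 had 0 for Il1b (4.05 to 5.37) and replicate 43 had 8.70 for Secisbp2 (8.91 to 8.99). In Ly6Ch F1R, replicate 47 had 11.87 for Rps20 (11.56 to 11.64) and replicate 49 had 4.87 for Kit (0 to 0.93).

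The F1T difference of 5 lists differed between cell types with a preset correlation of 0.01, in 7 comparisons of a list, and none did with an estimated correlation. It was lower in cMOP than in GMP for mitosis genes by a median of −0.10 (adjusted p = 0.993 with an estimated correlation). It was higher in Ly6Ch than in cMOP for nuclear oxidative phosphorylation by 0.14 (adjusted p = 0.977 with an estimated correlation) and for ribosomal protein genes by 0.27 (adjusted p = 0.143). It was higher in Ly6Ch than in GMP for nuclear oxidative phosphorylation by 0.14 (adjusted p = 0.660 with an estimated correlation), phagocytosis by 0.11 (adjusted p = 0.660), ribosomal protein genes by 0.23 (adjusted p = 0.481) and Ly6C-low monocyte genes by 0.83 (adjusted p = 0.660).

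Ribosomal protein genes were higher in Ly6Ch F1T by a median of 0.29. Lists of other genes matched on level and transcript length had a median of 0.11 (95% of lists 0.0616 to 0.145). Length was that of the longest annotated transcript of each gene, which need not be the one expressed. By that length, bias did not account for the whole rise in these libraries. The test cannot exclude it for the transcripts expressed. The upper bound lay only narrowly under the limit set, 0.5 times the ribosomal median. That range is over drawn genes and holds no spread between libraries, so level or length stays open as a cause of part of the rise. Admixed cMOP cells, which have more ribosomal protein transcripts, are excluded for replicates 41, 42 and 43: their 20 most abundant cMOP transcripts gave median cMOP shares of −0.0399, −0.0263 and −0.0274 (SE 0.0175, 0.0206 and 0.0184) above the F1R level, while their ribosomal protein genes would need 0.256, 0.186 and 0.285. For replicates 44 and 45 admixture cannot be told apart from other causes: the shares were 0.262 and 0.182 (SE 0.0675 and 0.0476) against 0.271 and 0.223 needed, although Mpo alone gave 0.0475 and 0.0345, and over all 5 libraries 64 of the 100 most cMOP-enriched genes were higher, with a median of 0.16 (0.0302 to 0.272). Depth is excluded as the whole cause: the difference in list mean was 0.230 ± 0.0488 (SE), and with depth as a covariate 0.225 ± 0.0578, which is 3.89 SE above 0. The covariate took the early granule difference from 0.20 to 0.0029, but the late neutrophil difference only from 0.525 to 0.483. In both of these lists F1T 44 and F1T 45 had the highest scores. Depth, like length, stays open as a partial cause. Untested and open are less mature monocytes within the gate, differences between litters and an effect of the father's infection.

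Libraries 44 and 45 of F1T lay apart from the rest in both cMOP and Ly6Ch. The gap on the first principal component to the library nearest in depth cannot exclude depth as a cause. It could only come out large, since these libraries already lay beyond all others on that component. It was 3.37 SD of the others or more for the 3 libraries inside the depth range of the others. For Ly6Ch F1T 44, which was deeper than all the others, it was 5.08 SD. Other libraries both shallower and deeper than each of the 3 lay with the rest, so depth alone did not set their position. Depth stays open as a partial cause for the 3, and as a cause for Ly6Ch F1T 44. For GMP cells in the cMOP gate, the 100 most GMP-enriched genes were compared with the median cMOP library. Their median deviations were only 0.0381 (SE 0.145) in F1T 44 and −0.0156 (SE 0.107) in F1T 45. Cd34, a progenitor gene, was at 747 and 912 normalized counts where the others had 1862 to 2661. Admixed GMP cells would raise such genes, so these values argue against a large share of them in these 2 cMOP libraries. A small share stays open. Neutrophil cells in the Ly6Ch gate may contribute and stay open: a share of 0.8 of the late neutrophil genes (12 of 15) lay above the median Ly6Ch library in both, S100a8 was at 56066 and 34891 where the others had 3279 to 7766, and S100a9 at 12019 and 6183 where the others had 462 to 1170. The labels name no batch, and no biological explanation was tested for these 2 libraries, which belong to the same group as 3 others.

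Splitting the same libraries into other groups of the same sizes showed where chance can be excluded. For cMOP against GMP, 2 of 100 splits, the real one included, gave as many genes as the real 1851, with 3040 as the highest of the others, and for Ly6Ch against cMOP 1 of 100, with 3275 genes against 1046. The number of lists called with a preset correlation was as large as the real 18 in 27 of 100 splits (highest other 24) and as large as the real 21 in 14 of 100 (highest other 24), so by this number alone chance was not excluded. These splits mix libraries of different cell types, and the number does not bear on the 7 and 11 lists called with an estimated correlation. For lists called between F1T and F1R chance was not excluded, with 82 of 100 splits giving at least the real 3 in cMOP (highest other 18) and 66 of 100 at least the real 6 in Ly6Ch (highest other 19). A real count of 0 genes is reached by any split, so the 100 of 100 in cMOP (highest other 56) and in Ly6Ch (highest other 1) say nothing about chance. In GMP the 10 splits are too few to give a share under 0.05, with 0 genes and 11 lists in the real split and at most 2 genes and 15 lists in the others (10 of 10 and 6 of 10 as large).

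For the difference of effect between cell types the real count of genes was also 0, which 100 of 100 splits reach by construction and which says nothing about chance. The highest other count was 1 for cMOP against GMP, 680 for Ly6Ch against cMOP and 5 for Ly6Ch against GMP. For lists chance was not excluded, since as many came from 93 of 100 splits (real 1, highest other 18), 82 of 100 (real 2, highest other 17) and 82 of 100 (real 4, highest other 18). Which libraries were grouped by the splits that called 56 and 680 genes, where the real ones called 0, was not examined. The cause of these counts was not tested.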

How the results depend on the processing

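Array weights, a mean value of at least 100, pseudocounts of 0.5 and 4, quantile normalization, other scalings of the list tests and leaving out the libraries numbered 44 and 45 were chosen after seeing the data. For each change below the cause was not tested, except that fewer genes were tested with a mean of at least 100. For F1T against F1R the 0 genes in GMP became 2 with array weights and 3 without libraries 44 and 45 (here F1T 45), and 1 fit of all 26 libraries gave 1 in cMOP (Filip1) and 3 in Ly6Ch (Ica1, Mmp2 and Pcdhgc4), chosen after their values were seen; the other settings run gave 0. A mean value of at least 100 left 819 genes (496 up, 323 down) for cMOP against GMP and 1787 (960 up, 827 down) for Ly6Ch against cMOP.

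With an estimated correlation the lists called were 0 in GMP, 0 in cMOP and 1 in Ly6Ch, 0 for each difference of effect, 7 for cMOP against GMP and 11 for Ly6Ch against cMOP. With fry they were 0, 0 and 1 for F1T against F1R, and for the differences 0 for cMOP minus GMP, 1 for Ly6Ch minus cMOP (ribosomal protein genes) and 0 for Ly6Ch minus GMP, against 25 for cMOP against GMP and 29 for Ly6Ch against cMOP. Voom values gave 3 lists for cMOP minus GMP. Without libraries 44 and 45, 10 lists were called in cMOP and 10 in Ly6Ch, 7 for cMOP minus GMP and 8 for Ly6Ch minus GMP, and each difference of effect had 1 gene (mt-Rnr1, Nr0b2 for Ly6Ch minus cMOP, and mt-Rnr1). The median of glycolysis genes in cMOP reversed to −0.056 and that of early granule genes in Ly6Ch to −0.091, and the ribosomal list's adjusted p with an estimated correlation was 0.416. With a reduced library size that p was 0.0393 and the median 0.25.

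Leaving out each library in turn gave 0 to 3 genes in GMP (3 without F1T 45) and 0 in every case in cMOP and Ly6Ch. It gave 0 to 1 for cMOP minus GMP and Ly6Ch minus GMP (mt-Rnr1 without GMP F1T 45) and 0 to 1 for Ly6Ch minus cMOP (Rtkn without cMOP F1T 42 or cMOP F1R 46, Ica1 without Ly6Ch F1T 44). The cell type comparisons gave 1768 to 1869 and 3148 to 3386 genes. Lists numbered 6 to 10 in GMP, 2 to 6 in cMOP, 5 to 11 in Ly6Ch, 0 to 6 for cMOP minus GMP, 2 to 5 for Ly6Ch minus cMOP, 2 to 7 for Ly6Ch minus GMP, 16 to 19 for cMOP against GMP and 21 in every case for Ly6Ch against cMOP. The ribosomal median in Ly6Ch ranged from 0.27 to 0.32 and its adjusted p with an estimated correlation from 0.0198 to 0.147. Effect correlations ranged from 0.0189 to 0.217 for cMOP with Ly6Ch, 0.0843 to 0.162 for GMP with cMOP and 0.0247 to 0.0777 for GMP with Ly6Ch.

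Replicate numbers recur across cell types. The numbers were not taken to pair the libraries, since not every pair correlated above 0.1, but that criterion cannot show libraries to be unpaired. Deviations of same-numbered libraries correlated above 0.1 in 3 of 10 pairs of cMOP and Ly6Ch (−0.0736 to 0.271). They did so in 1 of 6 of GMP and cMOP (0.0121 to 0.226) and 1 of 6 of GMP and Ly6Ch (−0.0243 to 0.124). The own number was the best match in 2 of 10, 4 of 6 and 2 of 6, a hint of pairing from the data and not the design. The main fits of all libraries treated them as independent, so their p-values would be affected if the numbers mark animals. With the number as a block the cell type comparisons gave 1842 and 3289 genes, the differences 0 genes, and cMOP minus GMP 3 lists. The DESeq2 test and fold changes were not run because the values are not counts, and the sex covariate was not run because the libraries were alike in it. Depth limits genes near the filter most, since 1 read is worth more in shallow libraries.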

Other observations

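Tnfsf13 and Lcn2 were set side by side in the 3 cell types, and the lists below named for libraries 44 and 45, only after their values were seen.

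Tnfsf13, which encodes the cytokine APRIL, was at 917 ± 66.3 normalized counts in F1T and 642 ± 62.2 in F1R (SD, n = 3 each) in GMP. All 3 F1T libraries (844 to 972) lay above all 3 F1R libraries (597 to 713), which chance gives in 10% of cases, counting both directions. In cMOP the F1T libraries (758 to 1004) also lay above the F1R libraries (531 to 645). In Ly6Ch the values were 1014 ± 151 and 759 ± 196 (SD, n = 5 each), with overlapping ranges of 825 to 1149 and 638 to 1097. The log2 difference was 0.52 in GMP, 0.57 in cMOP and 0.44 in Ly6Ch, and none passed adjustment over all genes by limma. Lcn2, which encodes lipocalin-2, differed by 0.75 in GMP, 0.55 in cMOP and 1.39 in Ly6Ch, where the F1T libraries spread from 283 to 7126 and the F1R libraries from 404 to 497. It belongs to the late neutrophil list, whose scores in Ly6Ch were highest in F1T 44 and F1T 45. Exons of Tnfsf13 overlap those of Tnfsf13os on the other strand and of the readthrough gene Tnfsfm13, so its values are uncertain. Libraries of the 3 cell types share replicate numbers, so these differences are not known to be independent of each other.

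The libraries numbered 44 and 45 also stood apart in lists that the F1T and F1R comparison did not call. Their scores for unfolded protein and amino acid response genes were 6.18 and 6.10 in Ly6Ch, where the other 8 libraries had 4.99 to 5.61, and 6.95 and 6.83 in cMOP, where the others had 5.79 to 6.53. In GMP library 45 had 7.05, where the other 5 had 6.34 to 6.57. Their glycolysis scores in Ly6Ch were 8.05 and 7.94 (others 7.28 to 7.68), their MHC class II scores 3.11 and 3.21 (others 3.40 to 4.38), and Cd74 was at 475 and 465 normalized counts (others 1267 to 2895).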
